A study of Malus domestica with 18 samples.

How the data were processed

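Leaf RNA was measured in apple plants of a Gala progeny, and 30 plants went into each of 18 samples. The samples form 6 groups of 3, from 3 nitrogen (N) statuses crossed with a spray of acibenzolar-S-methyl (ASM) or of water. ASM is a synthetic inducer of plant resistance that acts on the salicylic acid pathway. Per the labels' protocols, stranded mRNA libraries were sequenced on an Illumina instrument. Per the submitters' processing notes the reads were quantified with Salmon. Its version, the genome build and the annotation are not given in the sources used here.

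Per the file headers, each per-library file deposited by the authors holds, for 52311 gene IDs, an estimated count of reads that need not be whole, a TPM value and an effective length. The authors also deposited a table of the whole series, which holds whole-number counts in 18 columns. The estimated counts of the per-library files, rounded to whole numbers, were the values tested. TPM values were not tested. A name table of NCBI RefSeq genes with 51804 entries matched 0 of the 52311 IDs, and the files do not pair IDs with names. No gene is therefore named here, the gene lists fixed beforehand could not be tested, and only IDs are printed.

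The deposited sources differ in 2 ways. In 12 of the 18 columns of the series' table, 3629 IDs (6.94%) carry values that belong to other IDs of the same set in the per-library files, at a tolerance of 0.5 reads. The columns of the table for the N-resupplied ASM and N-resupplied water samples of replicate 1 also hold each other's values. Over 38417 IDs with a read in either library, the column named for the ASM sample matched its own file within 1 read at 7.78% of IDs and the water sample's file at 90.9%. The per-library files, whose sample is recorded, were used as labelled in the planned analysis. These samples are called the library labelled ASM and the library labelled water.

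Counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr by group) in R 4.3.3. All libraries entered 1 fit of 6 group means, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error (SE) of a log2 fold change is its size over the root of the F statistic. This fit of 18 libraries as labelled was fixed before the data were examined. A fit of 16 libraries, without the 2 in conflict, was added afterwards, when the files and the counts of calls with and without these libraries had been seen. Values are led by the 16-library fit because the 2 libraries cannot be placed from the labels alone. The planned total of called genes stands beside that of each comparison. Another fit placed the 2 libraries as the table's header does. The fits tested 32567 genes with 18 libraries and 32991 with 16. The common dispersion was 0.118 with 18 libraries as labelled, 0.0495 with 16, and 0.0519 with the table's placement.

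Alternatives were RLE factors, no filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, offsets from effective lengths, the series' table, a log2 fold threshold of 1, the libraries of the compared groups alone, and leaving out each library in turn. The IDs named were fixed by a rule: adjusted p under 0.05, a mean of at least 1 CPM over the compared libraries, no overlap between the groups, then the 2 highest and 2 lowest log2 fold changes. For the mean over N statuses, a direction shared by all 3 statuses took the place of the condition on overlap. The rule was applied to the 16-library fit. With the planned fit it would have named no ID for ASM within a status, since nothing was called. A fold against a group with 0 reads is a lower bound, computed against 3 reads over the group. With 1 to 3 reads the ratio has an exact 95% interval. Bounds and intervals cover counting error only.

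Same-numbered replicates deviated together. In the 16 libraries, the correlation of deviations from the group means was 0.205 to 0.565 over 18 pairs among the groups with 3 shared numbers, all above 0.1. Each of the 16 libraries correlated best with its own number. Between groups sharing 2 numbers it ranged from -0.0402 to 0.387, and with 18 libraries as labelled from -0.799 to 0.568. The pairing comes from the data and the shared numbers in the labels. The sample descriptions also carry a prefix (QU, RE or RS) that goes with the replicate number in all 6 groups. The leading counts and p-values do not use the pairing. In the 16-library fit the N-resupplied groups hold replicates 2 and 3 alone, so replicate differences enter their comparisons with the other N statuses. Blocked counts of called genes are given in the results where they differ by over 1.5 times. For ASM against water they were 12644 in high N, 12580 in N-limited and 13762 in N-resupplied plants, and 20198 for the mean.

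The test was run on simulated counts drawn from the means and dispersions of the 32991 genes, in the layout of the 16 libraries. At each fold 50 genes were changed, drawn from those with a mean of at least 1 CPM, so recovery at lower levels is not covered. Far fewer genes changed than were called for ASM, and the adjustment depends on that share. For ASM in N-limited plants it recovered 54% of genes changed 2-fold, 88% at 4-fold and 100% at 8-fold. For the difference of the ASM effect between N-limited and high N plants it recovered 16%, 74% and 98%. Recovery was 38%, 90% and 100% for N-resupplied against N-limited water plants and 34%, 92% and 98% for N-resupplied against high N water plants. It was 10%, 72% and 94% for the difference of the ASM effect between N-resupplied and high N plants. These sets were drawn without pairing of replicates. Per the series' design the 3 samples of a group are biological replicates; how their plants were grown apart is not given in the sources used here, so p-values measure the spread between these samples. No library was a copy of another of its group, since the lowest chi-square per gene between replicates was 20.04.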

Results

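The transcriptome of young apple leaves was measured to follow the response to ASM under 3 N statuses. High N plants received 7 mM N. N-limited plants were kept on 0.5 mM N for 12 days and sprayed after 10 days. N-resupplied plants were limited for 12 days and received N again for 24 h before the spray. Treated plants received 0.4 g/L of a product with 50% ASM, and control plants received water. Leaves were taken 2 days after the spray, so that N-limited and N-resupplied leaves were harvested on different days after the start of limitation. Each group held 3 libraries of 30 plants each. Library totals ranged from 26903457 to 38242043 estimated reads. Of 52311 gene IDs, 42349 had a read in at least 1 library. A gene with 0 reads can have up to 0.112 CPM in the shallowest library.

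The deposited sources disagree on which of the N-resupplied replicate 1 libraries was sprayed with ASM. A set of 2526 genes called at least 2-fold higher with ASM in both high N and N-limited plants was followed in the N-resupplied libraries. None of these was among the libraries compared to choose it. The 2 in conflict were not in the fit, while the others shared in its filter and dispersions. The mean log2 CPM of the set was 0.642 and 0.663 in the other N-resupplied water libraries and 4.01 and 3.59 in the other ASM libraries. The library labelled ASM, replicate 1, stood at 0.125 and the library labelled water, replicate 1, at 3.45. The 696 genes lowered in both other statuses stood at 3.66 in the library labelled ASM and at 2.25 in the library labelled water. Counts are therefore given without these libraries and, as planned, with all 18 as labelled.

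**Figure D1:**
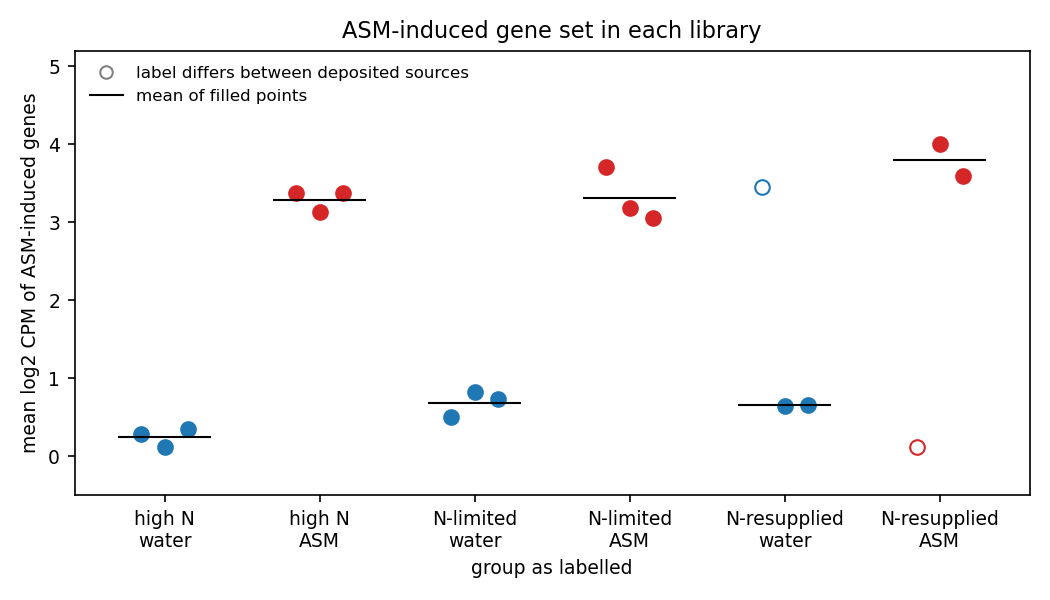
Mean log2 CPM (y axis) of 2526 genes induced by ASM in high N and N-limited plants, for each library of the 6 groups as labelled (x axis); open circles are the 2 libraries whose label differs between deposited sources and lines are means of the filled points. The separation in high N and N-limited groups follows from the choice of the set, while the open circles stand at 3.45 (labelled water) and 0.125 (labelled ASM).

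The first question was how leaves of high N plants responded to ASM. With 16 libraries, 5445 genes were higher and 4351 lower in ASM than in water plants. Of the higher genes 1115 changed at least 10-fold, against 13 of the lower ones. MD10G1027240 had 0 reads in the 3 water libraries and 33.0 ± 10.3 CPM (SD, n = 3) with ASM, at least 887-fold higher (edgeR adjusted p = 1e-06). MD16G1056600 also had 0 reads in water and reached 27.9 ± 19.3 CPM (SD, n = 3), at least 773-fold higher, or 455-fold without ASM replicate 1. MD10G1008700 fell from 4.87 ± 3.7 to 0.602 ± 0.146 CPM (SD, n = 3), a log2 fold change of -3.01 (SE 0.612), or -2.18 without water replicate 3. MD15G1227100 fell from 28.2 ± 10.3 to 3.53 ± 0.752 CPM (SD, n = 3), a log2 fold change of -2.99 (SE 0.399). In the series' table these log2 fold changes were 1.04 for MD10G1008700 and 0.326 for MD15G1227100. Both IDs are displaced there in the water columns and not in the ASM columns, so these values set different IDs against each other. The planned fit of 18 libraries called 0 genes in edgeR, with 9535 at an unadjusted p under 0.05, 0 by limma-voom and 4418 by DESeq2. Leaving out the library labelled N-resupplied ASM, replicate 1, gave 7198, and leaving out that labelled water, replicate 1, gave 4286. The 6 high N libraries alone, a fit fixed beforehand that uses neither disputed library, called 9277.

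In N-limited plants, 5533 genes were higher and 3978 lower with ASM. MD10G1027240 again had 0 reads in water, and stood at 40.7 ± 7.84 CPM (SD, n = 3) with ASM, at least 1330-fold higher. MD10G1027230 had 1 read over the 3 water libraries and 8826 with ASM, a ratio of 8097 with an exact 95% interval of 1450 to 320000. Its log2 fold change was 12.5, or 14.3 without N-limited water replicate 3, which held that read. MD09G1200900 fell from 5.22 ± 4.76 to 0.426 ± 0.319 CPM (SD, n = 3), and MD08G1119600 from 1.97 ± 0.95 to 0.261 ± 0.124 CPM (SD, n = 3). The call of MD09G1200900 was lost in 5 of the alternatives, among them those without N-limited water replicate 2 (edgeR adjusted p = 0.081), where its log2 fold change was -2.52 instead of -3.58, and without N-limited ASM replicate 2 (0.062). In the series' table its log2 fold change was 0.187 and that of MD08G1119600 was 1.87. There the water values of both IDs are displaced and their ASM values are not, so different IDs are set against each other. Planned values were 0 genes in edgeR, 9078 at an unadjusted p under 0.05, 0 by limma-voom and 3193 by DESeq2, against 8213 with the 6 N-limited libraries alone. Without the library labelled N-resupplied ASM, replicate 1, the planned fit gave 6307, and without that labelled water 2515. Without the N-limited ASM library of replicate 1, the 16-library count was 6090.

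In N-resupplied plants, with 2 libraries per group, 5867 genes were higher and 5220 lower with ASM. MD10G1027210 had 0 reads in water and 49.5 ± 3.82 CPM (SD, n = 2) with ASM, at least 1020-fold higher. MD10G1027240 reached 43.9 ± 10.4 CPM (SD, n = 2), at least 915-fold higher. MD00G1174400 fell from 5.9 ± 2.12 to 0.329 ± 0.367 CPM (SD, n = 2), and MD02G1123200 from 3.2 ± 1.5 to 0.202 ± 0.0891 CPM (SD, n = 2). With all 18 libraries as labelled, edgeR, limma-voom and DESeq2 each called 0 genes, with 722 at an unadjusted p under 0.05 in edgeR, and MD00G1174400 had a log2 fold change of 0.0468. With 16 libraries its log2 fold change was -4.09, or -3.32 without ASM replicate 2 and -6.33 without ASM replicate 3. In the series' table, where these IDs carry values of other IDs, the log2 fold change was -0.577 for MD10G1027210 and 3.68 for MD02G1123200. Without the library labelled ASM, replicate 1, the planned fit gave 2086, of which 672 were higher and 1414 lower. Leaving out the library labelled water, replicate 1, left the planned count at 0. With the placement of the table's header, 6956 genes were higher and 6579 lower. Without the N-resupplied ASM library of replicate 2, the 16-library count of 11087 fell to 6605, and with the 4 N-resupplied libraries alone it was 6202.

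**Figure D2:**
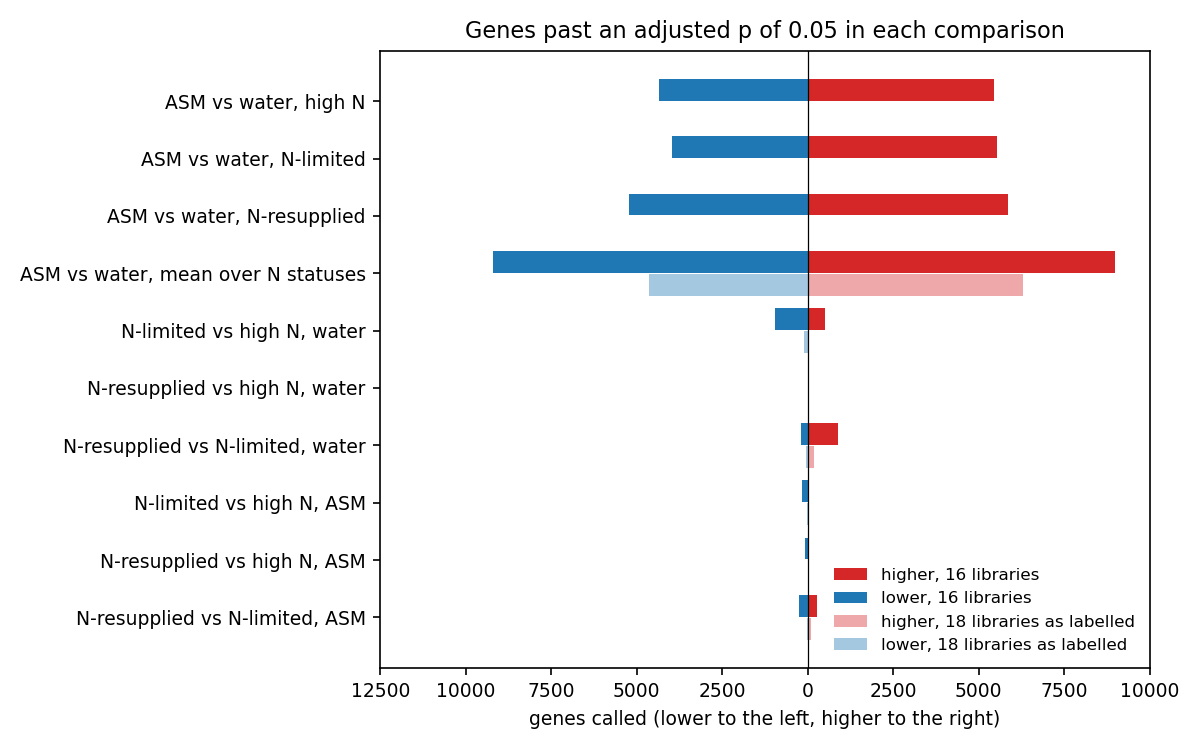
Genes past an adjusted p of 0.05 (x axis, lower to the left and higher to the right) in 10 comparisons (y axis), for 16 libraries (dark bars) and for 18 libraries as labelled (pale bars). Bars of the 3 comparisons of ASM within an N status are seen for 16 libraries alone, since 0 genes were called with 18 as labelled.

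The responses in the 3 N statuses compare separate libraries, though 1 fit gave the dispersions of all, and involved many of the same genes. In all 3 statuses 4143 genes were called higher and 2542 lower. Between high N and N-limited plants, 4405 higher genes were shared, where independent lists would share 913.2, and 2771 lower genes, against 524.6. Of the genes called in either direction in high N, 4 were called the opposite way in N-limited plants and 1 in N-resupplied plants. Across the 32991 genes, which are not independent replicates, log2 fold changes of the high N and N-limited comparisons had a Pearson correlation of 0.873. The planned fit called 0 genes in all 3 statuses. A group of 14 genes had at most 3 reads over the 8 water libraries and at least 1 CPM in each of the 8 ASM libraries, and 0 genes showed the opposite pattern.

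**Figure D3:**
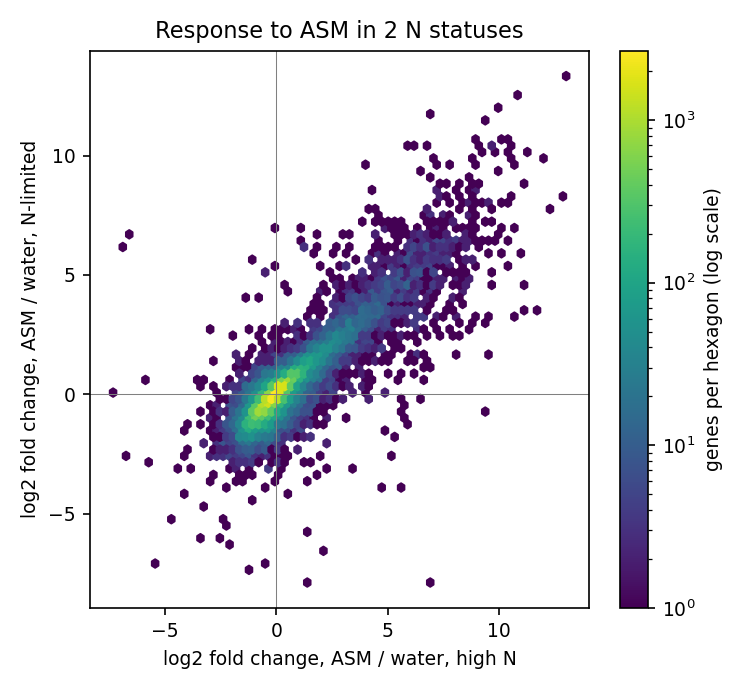
Log2 fold change of ASM over water in high N plants (x axis) and in N-limited plants (y axis) for 32991 genes of the 16-library fit; colour gives genes per hexagon on a log scale. Genes lie along the diagonal, with a Pearson correlation of 0.873 across genes.

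Averaged over N statuses, 8989 genes were higher and 9207 lower with ASM. MD10G1027240 had 0 reads in 8 water libraries and 38.6 ± 9.29 CPM (SD, n = 8) with ASM, at least 3120-fold higher. MD10G1027230 stood at 0.0163 ± 0.0263 CPM in water and 79 ± 37 CPM with ASM (SD, n = 8). MD13G1106200 fell from 26.5 ± 13.8 to 3.61 ± 2.68 CPM (SD, n = 8), and MD04G1174000 from 3.41 ± 2.78 to 0.997 ± 1.42 CPM (SD, n = 8). The log2 fold change of MD04G1174000 was -3.11, or -3.88 without N-resupplied ASM replicate 3. It is the mean of 3 status effects, while the pooled reads, scaled for depth, differed 3.26-fold. In high N the gene was not called (edgeR adjusted p = 0.19), and its N-resupplied ASM libraries held 0 and 1 reads. This gene was not called by the planned fit (edgeR adjusted p = 0.26). MD13G1106200 was not called in the series' table, where its values are displaced in part of the columns, with a log2 fold change of 0.252. The IDs MD10G1027230 and MD10G1027240 had whole-number estimates in 33.3% and 50% of the 18 libraries. A library with 0 reads counts as whole, so these shares overstate how often levels above 0 were unambiguous. Part of the reads of both IDs may be shared with similar genes, and their levels are uncertain. The same doubt holds for the other named IDs, whose shares ranged from 0%, as for MD09G1006500, to 72.2% for MD13G1076700. The planned fit called 6291 higher and 4651 lower. Genes induced in high N plants, chosen in the high N libraries, took 2.26% ± 0.2 of reads in high N water libraries and 12.2% ± 0.95 in high N ASM libraries (SD, n = 3). The same genes took 3.39% ± 0.24 and 13% ± 2.3 in N-limited plants (SD, n = 3), and 2.89% ± 0.071 and 17.4% ± 4 in N-resupplied plants (SD, n = 2).

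Whether N status changed the response to ASM was tested as the difference of the ASM effects. For N-limited minus high N, edgeR called 0 of 32991 genes with 1114 at an unadjusted p under 0.05, where chance gives 1650; DESeq2 called 27 and limma-voom 0. For N-resupplied minus high N, edgeR called 0 with 1120 unadjusted, DESeq2 1 and limma-voom 0. For N-resupplied minus N-limited, edgeR called 0 with 1825 unadjusted, DESeq2 24 and limma-voom 0. The planned fit also called 0 in each, with 402, 1083 and 841 unadjusted, while limma-voom called 0 and DESeq2 6, 11 and 10. All of these 6, 11 and 10 genes were at least 10-fold. Their median log2 values were 18 for higher and -18.7 for lower genes in the first difference, then -22.2 and -22.4. The 1 DESeq2 call for N-resupplied minus high N with 16 libraries stood at -18.5. Values this extreme are not read here as sizes of an effect. Same-numbered replicates deviated together, and with the replicate block of the 16 libraries edgeR called 0 in each, with 1934, 1953 and 3272 unadjusted, above the 1650 of chance. In the series' table, which holds values displaced between IDs, edgeR called 17, 1625 and 1759 with the 16 libraries. The precision was limited. In the order above, the median SE was 0.322, 0.362 and 0.361, and the 95% interval lay within 1 log2 unit for 54.7%, 48.1% and 45.1% of genes. Among 3668 genes induced at least 2-fold on average it did so for 20.5%, 17.3% and 13.1%. The median difference of these genes was -0.34, 0.18 and 0.49, and that of 2540 genes lowered at least 2-fold was -0.044, -0.58 and -0.56. These medians were not tested.

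N limitation was examined in water plants. Against high N, 497 genes were higher and 971 lower in N-limited leaves. MD09G1006500 fell from 362 ± 164 to 2.36 ± 0.497 CPM (SD, n = 3), a log2 fold change of -7.26 (SE 0.735, edgeR adjusted p = 0.00017). MD07G1115200 had 2.68 ± 3.65 CPM (SD, n = 3) in high N and 0 reads in N-limited leaves, at least 86.9-fold lower. Of its 215 reads in high N, replicate 3 held 183, and without this library the bound was 19.2-fold. Its call was lost in 4 alternatives, among them those without N-limited water replicate 2 (edgeR adjusted p = 0.055) and replicate 3 (0.065). MD07G1291700 rose from 1.53 ± 0.529 to 17.2 ± 5.26 CPM (SD, n = 3), and MD11G1141700 from 0.528 ± 0.532 to 6.53 ± 4.18 CPM (SD, n = 3), the latter with its call lost in 8 alternatives and a log2 fold change of -1.52 in the series' table. These included leaving out high N water replicate 1 (edgeR adjusted p = 0.15) or 3 (0.11), or N-limited water replicate 1 (0.086) or 2 (0.078). Without high N water replicate 2 its log2 fold change was 4.85 instead of 3.61. In the series' table, where MD07G1291700 and MD11G1141700 carry values of other IDs, the former was not called (edgeR adjusted p = 0.93). With the replicate block 3134 genes were called, and the planned fit called 20 higher and 107 lower. The count of 1468 fell to 539 without high N water replicate 1, to 934 without replicate 3 of that group, to 673 without N-limited water replicate 2 and to 532 without N-limited water replicate 3.

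After resupply, 896 genes were higher and 210 lower than in N-limited water plants. MD14G1086500 had 0 reads in N-limited leaves and 4.81 ± 2.74 CPM (SD, n = 2) after resupply, at least 153-fold higher, or 94.3-fold without N-resupplied replicate 3. MD13G1076700 also had 0 reads and reached 3.86 ± 2.88 CPM (SD, n = 2), at least 131-fold higher, or 59.7-fold without N-resupplied replicate 2. MD12G1178500 fell from 45.4 ± 15.5 (n = 3) to 3.81 ± 2.52 CPM (SD, n = 2), and MD13G1026000 from 5.9 ± 2.61 (n = 3) to 0.452 ± 0.0454 CPM (SD, n = 2). The call of MD13G1076700 was lost without N-resupplied water replicate 2 (edgeR adjusted p = 0.14), without N-limited water replicate 3 (0.058) and in DESeq2 (0.093). That of MD13G1026000 was lost without N-resupplied water replicate 2 (edgeR adjusted p = 0.052) and in the planned fit (0.076). The log2 fold change of MD12G1178500 was -3.56, or -4.48 without N-resupplied water replicate 2. Its call was lost in the planned fit (edgeR adjusted p = 0.44) and in the series' table (0.33), where it carries values of another ID. With the replicate block 2405 genes were called, and the planned fit called 186 higher and 58 lower. Without N-resupplied water replicate 2 the count of 1106 fell to 91, without replicate 3 of that group to 458, without N-limited water replicate 1 to 681, without replicate 2 of that group to 709 and without its replicate 3 to 427.

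Against high N, N-resupplied water leaves differed in 1 called gene. MD00G1082300 stood at 1.78 ± 0.376 CPM (SD, n = 3) in high N and 5.4 ± 0.363 CPM (SD, n = 2) after resupply (edgeR adjusted p = 0.016). Both N-resupplied libraries stood above all 3 high N libraries. Few calls do not show equal levels. The IDs named for resupply were not called here, yet MD14G1086500 had 0, 0 and 4 reads in high N and 95 and 193 after resupply. MD13G1076700 had 0, 2 and 0 against 195 and 52, and MD12G1178500 had 866, 633 and 513 against 185 and 58. MD13G1026000 had 22, 51 and 17 against 16 and 12. With the block 27 genes were called, DESeq2 called 191 and limma-voom 0, and 2284 had an unadjusted p under 0.05 where chance gives 1650. The planned fit called 0 in edgeR, with 3340 unadjusted, 0 by limma-voom and 554 by DESeq2. The 95% interval lay within 1 log2 unit for 63.5% of genes. The count was 0 without high N water replicate 1 or 2 or N-resupplied water replicate 2 or 3, and the call of MD00G1082300 was lost in 8 alternatives. It was 20 without high N water replicate 3, 26 without N-resupplied ASM replicate 2 or 3, 3 without N-limited water replicate 1 or 2, and 2 without high N ASM replicate 1 or N-limited ASM replicate 3.

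Of 1468 genes called in limitation, 697 were called the opposite way after resupply. Of these, 597 were lower in limitation and higher after resupply, where independent lists would give 26.4. The other 100 were higher and then lower, against 3.16. Against high N, the 971 lowered genes had a median log2 fold change of -0.0458 after resupply. The 497 raised genes kept a median of 0.409 there, and 421 of them stood above high N. That comparison shares the high N libraries with the calls. The limitation and resupply comparisons both use the N-limited water libraries, so part of the excess may come from them. The covariance of the log2 fold changes was -0.163, against -0.059 to -0.0547 in 20 simulated sets with no effect and without pairing of replicates. With the replicate effects kept, 20 sets gave -0.0451 to -0.04. Sets with limitation kept and N-resupplied water plants made equal to N-limited ones, without pairing, gave -0.0629 to -0.0554. In 5 sets without pairing, with no effect or with this equality, 0 genes were reversed. The 3 N-limited water libraries do not allow at least 2 for each comparison, so 1 was set in 1 comparison and the other 2 in the other, in 6 ways. The covariance was then -0.132 to -0.0513, against -0.00398 to 0.0426 in the simulated sets with replicate effects. Each division leaves a single N-limited library in 1 comparison. With the block 1528 genes were reversed, and the planned fit gave 85. In ASM plants, which share no library with the calls, the 971 lowered genes had a median log2 fold change of 0.4 after resupply and 121 were called higher, where independent lists would give 7.92. The 497 raised genes had a median of -0.088 there, and 31 were called lower against 3.81. The counts of 121 and 31 come from 269 genes called higher and 253 lower under ASM. With the libraries of these 2 groups alone, 24 genes were called higher and 5 lower. The count of 697 fell to 74 without N-resupplied water replicate 2 and to 311 without replicate 3 of that group. It fell to 464, 338 and 219 without N-limited water replicate 1, 2 and 3, and to 324 without high N water replicate 1.

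**Figure D4:**
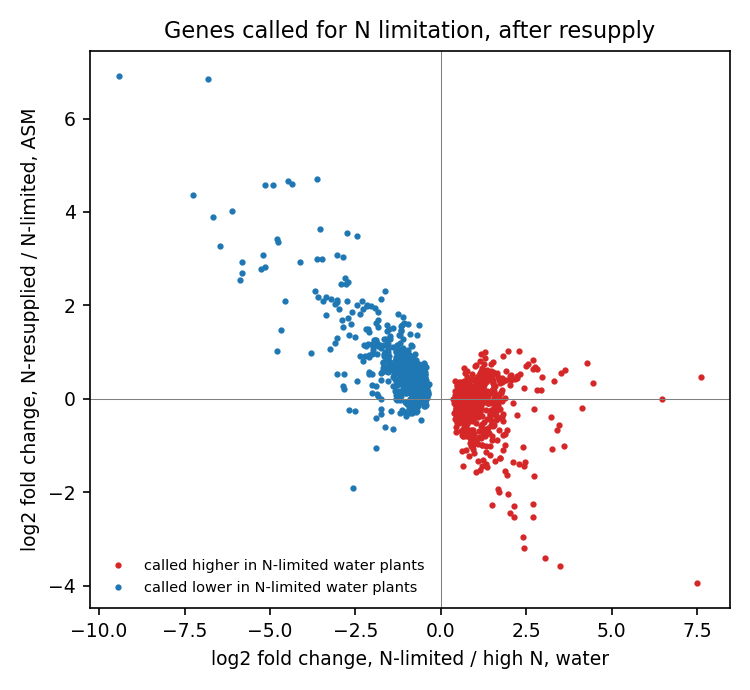
Log2 fold change of N-limited over high N plants in water (x axis) and of N-resupplied over N-limited plants under ASM (y axis) for 1468 genes called in the first; red points were called higher and blue points lower. The 971 blue points have a median of 0.4 and the 497 red points a median of -0.088 on the y axis.

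Among ASM plants, N-limited leaves had 42 genes higher and 170 lower than high N leaves, and 1379 were called with the block. Of the 971 genes lowered by limitation in water, 962 were also lower under ASM, 157 of them called, where independent lists would give 5. N-resupplied leaves had 45 genes higher and 77 lower than high N leaves (1038 with the block) and 269 higher and 253 lower than N-limited leaves (2539 with the block). The planned fit called 13, 0 and 125 genes in these comparisons. For N-resupplied against high N under ASM the planned fit had 1346 genes at an unadjusted p under 0.05, 75 by DESeq2 and 0 by limma-voom. These counts rest on few libraries. For N-limited against high N, the 212 genes fell to 65, 41 and 128 without high N ASM replicate 1, 2 and 3, to 92, 24 and 89 without N-limited ASM replicate 1, 2 and 3, and to 139 without high N water replicate 1. For N-resupplied against high N, the 122 genes became 1671 without N-resupplied ASM replicate 3 and 0 without its replicate 2 or without high N ASM replicate 1 or 2. They became 57 without high N water replicate 1, 77, 45 and 39 without N-limited water replicate 1, 2 and 3, and 51 without N-resupplied water replicate 2 or 3. For N-resupplied against N-limited, the 522 genes became 2035 without N-resupplied ASM replicate 3, 44 without its replicate 2, 194 without N-limited ASM replicate 2, and 69 higher and 32 lower without N-limited ASM replicate 3.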

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

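All tests in this part were chosen after the result was seen. The library labelled N-resupplied water, replicate 1, which the 16-library comparisons leave out, carried a signal above the control level. Its mean log2 CPM over the 2526 ASM-induced genes was 3.45, while the highest of the other water libraries stood at 0.831 and the lowest of the other ASM libraries at 3.05. The library labelled N-resupplied ASM, replicate 1, stood at 0.125. Both of the 2 libraries thus lay beyond the edge of the other treatment, which is what labels of the 2 libraries exchanged in the per-library deposit would give. A mixture is argued against in the library labelled ASM, whose fraction of ASM material, from the share of reads in genes induced in high N, was -0.036 with a spread of 0.038 over the other water libraries. In the library labelled water this fraction was 0.782, with a spread of 0.28 between the other 2 N-resupplied ASM libraries, so a mixture stays open there. A lack of response in the plants labelled ASM together with an induced state in those labelled water also stays open: at most 7.8% of the values in the table's columns match the library's own file, but the table's header could be wrong by itself. An exchange of labels is a candidate explanation. The levels of the induced set in both libraries go with the placement of the table's header. So do those of the 696 lowered genes, 3.66 in the library labelled ASM and 2.25 in that labelled water. The common dispersion was 0.118 as labelled and 0.0519 with that placement. These values do not tell an exchange of labels from a state of the plants, so they do not decide which deposited source is right.

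The series' table holds 3629 IDs whose values in 12 columns belong to other IDs of the set. If rows of the table had been reordered, these IDs would lose their rank correlation across the 2 blocks of columns, and it was at most 0.021 over 72 pairs of columns. In the per-library files the same IDs had a lowest rank correlation of 0.628, which argues against misplaced values there. The set is not a random one: 71.3% of the 3668 genes called at least 2-fold higher with ASM on average are in it, against 12.9% of the 2540 lowered genes and 1.07% of the 14795 genes not called. A reordering of a list chosen for its response to ASM may account for this, and why it happened was not tested.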

How the results depend on the processing

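The alternatives on 16 libraries (their fold threshold by direction), the table's placement, and leaving out libraries of groups not compared were chosen after seeing the data. For the shared response and the reversal only the fold threshold and the replicate block were fixed beforehand, and for the other comparisons the rest were. Totals of called genes are given where they moved by over 1.5 times, and their causes were not tested except where fewer libraries or a stricter threshold are the change itself. In the series' table the high N ASM and N-limited ASM columns hold no displaced values, and those of the other groups do. Its totals for comparisons across this divide set different IDs against each other. The same placement without displaced values gave 48 and 695 for N-resupplied ASM against high N and N-limited ASM. It gave 0 for each difference of the ASM effect. Tests of gene lists were not run, since no ID has a name. With 18 libraries as labelled the planned totals were 0 for each N status, 10942 for mean ASM and 127, 0 and 244 for the N comparisons in water. A log2 fold threshold of 1 gave 3318 for mean ASM. DESeq2 gave 4418 for ASM in high N, 3193 for ASM in N-limited, 495 for N-limited against high N in water, 554 for N-resupplied against high N in water, 1317 for N-resupplied against N-limited in water, 128 for N-limited against high N under ASM, 75 for N-resupplied against high N under ASM, 656 for N-resupplied against N-limited under ASM, 6 for the ASM effect N-limited minus high N, 11 for the ASM effect N-resupplied minus high N, 10 for the ASM effect N-resupplied minus N-limited and 294 for the reversal. The replicate block gave 432 for N-resupplied against N-limited in water, 30 for N-limited against high N under ASM and 238 for N-resupplied against N-limited under ASM. The series' table gave 9699 for ASM in high N, 9982 for ASM in N-limited, 13607 for ASM in N-resupplied, 18880 for mean ASM, 1288 for N-limited against high N in water, 9 for N-resupplied against high N in water, 1994 for N-resupplied against N-limited in water, 248 for N-limited against high N under ASM, 3365 for N-resupplied against high N under ASM, 4284 for N-resupplied against N-limited under ASM, 12 for the ASM effect N-limited minus high N, 1767 for the ASM effect N-resupplied minus high N, 1928 for the ASM effect N-resupplied minus N-limited, 6037 for the shared response and 887 for the reversal. The libraries of the compared groups alone gave 9277 for ASM in high N, 8213 for ASM in N-limited, 856 for N-limited against high N in water, 45 for N-resupplied against N-limited in water, 52 for N-limited against high N under ASM and 0 for N-resupplied against N-limited under ASM. Without the 2 libraries in conflict there were 9796 for ASM in high N, 9511 for ASM in N-limited, 11087 for ASM in N-resupplied, 18196 for mean ASM, 1468 for N-limited against high N in water, 1 for N-resupplied against high N in water, 1106 for N-resupplied against N-limited in water, 212 for N-limited against high N under ASM, 122 for N-resupplied against high N under ASM, 522 for N-resupplied against N-limited under ASM, 6685 for the shared response and 697 for the reversal. With the table's placement there were 9845 for ASM in high N, 9502 for ASM in N-limited, 13535 for ASM in N-resupplied, 19059 for mean ASM, 1400 for N-limited against high N in water, 12 for N-resupplied against high N in water, 2040 for N-resupplied against N-limited in water, 219 for N-limited against high N under ASM, 48 for N-resupplied against high N under ASM, 695 for N-resupplied against N-limited under ASM, 6994 for the shared response and 950 for the reversal. Leaving out 1 library at a time gave 0 to 7198 for ASM in high N, 0 to 6307 for ASM in N-limited, 0 to 2086 for ASM in N-resupplied, 7163 to 16407 for mean ASM, 37 to 329 for N-limited against high N in water, 0 to 20 for N-resupplied against high N in water, 57 to 632 for N-resupplied against N-limited in water, 0 to 32 for N-limited against high N under ASM, 0 to 32 for N-resupplied against high N under ASM, 15 to 237 for N-resupplied against N-limited under ASM, 0 to 1257 for the shared response and 25 to 196 for the reversal.

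With 16 libraries RLE factors and length offsets kept every total within 1.5 times. A log2 fold threshold of 1 gave 3038 for the shared response, 221 for the reversal, 3230 for ASM in high N (higher), 2850 for ASM in N-limited (higher), 3620 for ASM in N-resupplied (higher), 3668 for mean ASM (higher), 257 for N-limited against high N in water (higher), 365 for N-resupplied against N-limited in water (higher), 20 for N-limited against high N under ASM (higher), 1359 for ASM in high N (lower), 1389 for ASM in N-limited (lower), 3087 for ASM in N-resupplied (lower), 2540 for mean ASM (lower), 312 for N-limited against high N in water (lower), 128 for N-resupplied against N-limited in water (lower) and 81 for N-limited against high N under ASM (lower). Without the filter there were 25 for N-resupplied against high N in water. DESeq2 gave 2542 for N-limited against high N in water, 191 for N-resupplied against high N in water, 2048 for N-resupplied against N-limited in water, 903 for N-limited against high N under ASM, 1499 for N-resupplied against high N under ASM, 1662 for N-resupplied against N-limited under ASM, 27 for the ASM effect N-limited minus high N, 1 for the ASM effect N-resupplied minus high N, 24 for the ASM effect N-resupplied minus N-limited and 1182 for the reversal. Limma-voom gave 0 for N-resupplied against high N in water. The replicate block gave 3134 for N-limited against high N in water, 27 for N-resupplied against high N in water, 2405 for N-resupplied against N-limited in water, 1379 for N-limited against high N under ASM, 1038 for N-resupplied against high N under ASM, 2539 for N-resupplied against N-limited under ASM and 1528 for the reversal. The series' table gave 3 for N-resupplied against high N in water, 3805 for N-resupplied against high N under ASM, 4025 for N-resupplied against N-limited under ASM, 17 for the ASM effect N-limited minus high N, 1625 for the ASM effect N-resupplied minus high N and 1759 for the ASM effect N-resupplied minus N-limited. The libraries of the compared groups alone gave 6202 for ASM in N-resupplied, 856 for N-limited against high N in water, 0 for N-resupplied against high N in water, 688 for N-resupplied against N-limited in water, 52 for N-limited against high N under ASM, 0 for N-resupplied against high N under ASM and 29 for N-resupplied against N-limited under ASM. All 18 as labelled gave 0 for ASM in high N, 0 for ASM in N-limited, 0 for ASM in N-resupplied, 10942 for mean ASM, 127 for N-limited against high N in water, 0 for N-resupplied against high N in water, 244 for N-resupplied against N-limited in water, 13 for N-limited against high N under ASM, 0 for N-resupplied against high N under ASM, 125 for N-resupplied against N-limited under ASM, 0 for the shared response and 85 for the reversal. Leaving out 1 library at a time gave 6090 to 10184 for ASM in N-limited, 6605 to 11275 for ASM in N-resupplied, 532 to 1749 for N-limited against high N in water, 0 to 26 for N-resupplied against high N in water, 91 to 1451 for N-resupplied against N-limited in water, 24 to 283 for N-limited against high N under ASM, 0 to 1671 for N-resupplied against high N under ASM, 44 to 2035 for N-resupplied against N-limited under ASM and 74 to 912 for the reversal. Where leaving out a library left 1 in an N-resupplied group, that library is assumed to vary like the other groups. The replicate block changed no other total by over 1.5 times. In the series' table, where their values are displaced, the log2 fold change changed sign for MD10G1008700 (1.04), MD15G1227100 (0.326), MD09G1200900 (0.187), MD08G1119600 (1.87), MD10G1027210 (-0.577), MD02G1123200 (3.68), MD13G1106200 (0.252) and MD11G1141700 (-1.52), none of them past the threshold there. With all 18 libraries as labelled, MD00G1174400 had 0.0468. Depth limits genes near 0.112 CPM, the level that 0 reads allow in the shallowest library.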

Other observations

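The tests of the overlap between N limitation and ASM, of the divided N-limited libraries, and of splits for ASM in N-resupplied plants were chosen after the result was seen. The splits for the mean ASM effect, drawn within N statuses, and those for the differences of the ASM effect, drawn between N statuses, were drawn again after a first draw, which held repeated splits, had been seen. Genes raised by N limitation were mostly genes raised by ASM. Of 497 genes higher in N-limited than in high N water plants, 337 were also called higher with ASM in N-resupplied plants, where independent lists would share 88.38, and 18 were called lower, against 78.64. Of 971 genes lowered by limitation, 608 were lowered by ASM, against 153.6, and 44 were raised, against 172.7. These comparisons have no library in common, and they rest on the 16 libraries, since the planned fit called 0 genes for ASM in N-resupplied or high N plants. The 896 genes raised by resupply over N-limited plants in water included 587 that ASM lowered in high N plants, against 118.2 in independent lists, and the 210 genes lowered by resupply included 64 that ASM raised, against 34.66.

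An effect shared by the 2 conditions may account for the overlap. The Pearson correlation across 32991 genes between log2 fold changes of limitation in water and of ASM in N-resupplied plants was 0.284 (Spearman 0.316). It comes from the comparisons that gave the overlap, so it describes the overlap and is no separate evidence. With limitation measured under ASM it was 0.0924, below 0.1, with a Spearman correlation of 0.238, so the explanation stays open. Harvest day after the start of limitation differed between N-limited and N-resupplied plants. Leaf age, and the harvest day of high N plants on that scale, are not given in the labels. Both stay open.

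Of 22760 pairs of consecutive tested IDs in the files' sorted order, 919 were both called higher with ASM in high N, against 620.4 expected when calls were shuffled, a ratio of 1.48. A test for reads shared between near-identical copies was void: 17 pairs had whole-number estimates in both IDs, and the ratio among them was 0, with 0 pairs called.

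For the reversal after resupply, the covariance of -0.163 lay below the range of -0.059 to -0.0547 in 20 simulated sets with no effect. Those sets were drawn without the pairing of same-numbered replicates, and with replicate effects kept the range was -0.0451 to -0.04. With the N-limited libraries divided so that the comparisons shared none, and 1 of them resting on a single N-limited library, the covariance nearest 0 of the 6 divisions was -0.0513, just past the bound of -0.05 set for it, while the simulated sets gave -0.00398 to 0.0426. In ASM plants, which share no library with the calls, 121 of the 971 lowered genes were called higher after resupply, against 7.92 in independent lists, and 31 of the 497 raised genes were called lower, against 3.81. These 2 counts depend on the fit of 16 libraries: with the libraries of the 2 groups alone, 24 genes in all were called higher and 5 lower. The covariances and the calls under ASM argue against the shared N-limited libraries as the whole source, and a part from them stays open. The counts of reversed genes had been seen before these tests.

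For each comparison of 2 groups, the 6 libraries as labelled make 10 splits, too few for a share under 0.05. The real split called 9277 genes for ASM in high N, 8213 in N-limited plants, 856 for N-limited against high N in water, 45 for N-resupplied against N-limited in water and 52 for N-limited against high N under ASM. In each of these 1 split, the real one, reached that count and the highest other split called 0. For N-resupplied against high N in water and under ASM, and for N-resupplied against N-limited under ASM, the real split and the highest other both called 0, so that 10 of 10 reached the count. For ASM in N-resupplied plants the real split called 0 and the highest other, which exchanges the 2 replicate 1 libraries, called 10362. That split is the placement of the table's header, whose count was known, so it restates the structure of the samples described for these libraries and does not test it. For the mean ASM effect with 18 libraries as labelled, 2 of 25 splits drawn within N statuses reached the real count of 10942. The other one called 11579 and moves the library labelled water, replicate 1, to the ASM group in exchange for ASM replicate 3. In both splits, the N-resupplied ASM group holds 1 library at the water level, and the water group holds 1 at the ASM level. Similar counts follow from that, so this test cannot decide on chance and does not exclude it. For the differences of the ASM effect the real count was 0, so all 25 of 25 splits reached it, and the highest others called 438, 26 and 0, where no other split of the first draw had called a gene. The split with 438 exchanges all high N and N-limited ASM libraries and so measures the effect of N status.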
